A study of Mus musculus with 26 samples.

How the data were processed

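Gene expression was measured in FE1 cells, an epithelial cell line from mouse lung, after exposure to a coal tar reference mixture in DMSO. Per the labels, cells at passage 14 were grown for 72 h to 70% confluence and kept without serum for 24 h before exposure. They were exposed for 6 h to 1 or 4 mg/ml coal tar or to DMSO alone, washed, and incubated for another 4 or 8 h. For each array 2.5 µg of RNA was labelled with Cy5 and hybridised to an Agilent mouse array together with a Cy3-labelled reference pool made from 11 mouse cell lines. Replicates were separate exposure days of the same cell line, and the labels state that a shared replicate number marks a shared exposure day. There were 26 arrays in 6 groups over 5 days.

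Per the file headers, the quantification files hold the pixel intensity of each channel, as the median signal and the median local background of each spot, written by ImaGene 7.5.0. The raw intensity columns deposited in the processed tables equalled these signal medians without background subtraction. The normalized intensity columns and the log2 ratio of sample over reference were made by the authors within each array by a method that is not stated. The deposited whole-series table holds the same log2 ratios, with differences of at most 5.0e-08.

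The arrays carried 22575 spots, of which 21318 spots for 20868 probes were not controls. The symbol column of the array table gave 18235 probes with 1 gene symbol, 30 with several and 2603 with none. Of the probes with 1 symbol, 18022 were given the current symbol of their gene identifier. Another 213, whose identifier was not matched, kept the symbol of that column. A further 504 probes were matched to a gene through their transcript accession, leaving 2099 unmatched.

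Starting from the quantification files, both channels were background corrected with the normexp method (offset 50). The log2 ratio of Cy5 over Cy3 was then normalized within each array by loess, using limma 3.58.1 in R 4.3.3. Control spots and spots marked as outliers by the image software received weight 0, marked spots were treated as missing, and the spots of a probe were averaged. A probe was kept when its Cy5 median exceeded the background median by more than 2 background SDs on at least 4 of the 26 arrays, 4 being the size of the smallest group. This kept 14644 probes and removed 6224. Another 225 had fewer than 2 values in a group, so 14419 probes for 12597 genes were tested.

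A linear model with 1 mean per group was fitted to all 26 arrays with limma, with empirical Bayes moderation and statmod 1.5.0 where an exposure-day correlation was estimated. The 9 comparisons were each concentration against DMSO at each time, the concentrations against each other at each time, the change of each concentration's effect between times, and DMSO at 8 h against 4 h. All tests were two-sided. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 over all probes tested. If no probe changed, a share of about 0.05 of the probes would have an unadjusted p under 0.05. Values of rises and falls given without the word fold are log2 differences. Reported errors are SE of the fitted difference, and n is given as coal tar arrays and DMSO arrays. Where every array of a group lay under the background limit for a gene, a fold bound was computed against that limit from the Cy5 channel. No fold is given where the bound was under 1 or above the fitted fold. The bound is given without a sampling error, so the words at least refer to the background limit alone. For Cyp1a1 the bound lay above the lower 95% limit of the fitted fold in each coal tar comparison. Saturated spots were kept at their value.

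To check whether the numbers pair the arrays, residuals from the group means were correlated over 8860 probes. The mean r was 0.12 for 56 pairs from the same day and -0.030 for 225 pairs from different days, and the consensus correlation within days was 0.088. The comparisons were therefore also fitted with the day as a block.

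A total of 25 gene lists were fixed before the data were examined, along with the grouping, the comparisons, the named-gene rule and most of the other settings tried. The lists covered the aryl hydrocarbon receptor (AhR) battery, Nrf2 antioxidant genes, p53 targets, DNA repair, DNA replication and G1/S, mitosis and G2/M, histones, inflammatory cytokines and chemokines, and other secreted growth factors and proteases. They also covered the unfolded protein response and ATF4, heat shock proteins, cholesterol synthesis, fatty acid and triglyceride metabolism, hypoxia and glycolysis, interferon response, immediate early genes, and extracellular matrix. The rest were metallothioneins and phase II transferases, circadian clock, ribosomal proteins, and markers of lung epithelium, epithelium in general, mesenchyme, leukocytes and endothelium. Each list was compared with the other genes by camera with a preset correlation of 0.01, adjusted over 100 tests (25 lists by 4 coal tar comparisons). Camera with an estimated correlation and fry were run beside it. A list is said to pass by camera with the preset correlation unless stated otherwise, and the fry results are not given here.

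Genes were named by a fixed rule. A gene needed a probe with 1 symbol that was not a clone, RIKEN or predicted-gene name. Named were the 6 largest rises and the 6 largest falls that passed in each coal tar comparison with no overlap between the groups' arrays, and up to 3 members that passed from each list. Cyp1a1, Cyp1b1, Nqo1, Tiparp, Ahrr, Cdkn1a, Mdm2 and Hmox1 were always named. In a comparison where no probe passed, up to 5 genes with the smallest p were named.

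The procedure was tested on simulated data with normal noise at the SD estimated for each probe and 200 changed probes per run in 5 runs. It recovered 4-fold changes in 98.2% of cases for 1 mg/ml at 4 h, 97.0% for 4 mg/ml at 4 h, 97.9% for 1 mg/ml at 8 h and 99.1% for 4 mg/ml at 8 h. For 2-fold changes the shares were 37.9%, 35.8%, 47.8% and 40.3% in the same order, and for 1.5-fold changes 5.37%, 3.58%, 5.67% and 7.46%. False calls made up 6.14%, 3.58%, 3.44% and 4.84% of the calls. The simulated noise was independent between probes and arrays and held no exposure-day or session effect. These rates therefore describe such noise and may not hold for the real arrays.

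Other settings tried were no background correction, an offset of 10, median centring without loess, loess with quantile-matched average intensities, and the Cy5 channel alone after quantile normalization. The authors' log2 ratios, no filter on dim probes, and a filter needing signal on all 26 arrays were also run. Among the model choices were the exposure day as a fixed block or random effect, array weights, a trended and robust prior, an added 1.5-fold minimum, the quantification session as a block, and only the compared groups in the fit. Each array and each day was left out in turn, the lists were tested with other correlations and with a mean over a gene's probes, and DMSO arrays were split for the overlaps. Settings chosen after the data were seen were outlier-marked spots kept, and leaving out either the 2 arrays whose image numbers are exchanged or 5 arrays with weak signal. For the lists they also included the session as a block and the fit without 1 mg/ml 4 h replicate 3. The headers placed the arrays in 6 quantification sessions, taken as batches. Ahrr was not tested, since it exceeded background on 3 of 26 arrays. Control spots, the Cy3 channel by itself and the authors' spot marks were not analysed here.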

Results

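Transcript levels were measured in FE1 mouse lung epithelial cells exposed to coal tar, a mixture rich in polycyclic aromatic hydrocarbons. At 4 h after exposure there were 4 DMSO arrays, 4 arrays with 1 mg/ml coal tar and 4 with 4 mg/ml. At 8 h there were 4 DMSO arrays and 5 for each concentration. The median Cy5 signal per array ran from 467.2 to 1476, and between 40.7% and 79.5% of the gene spots stood well above background. On 5 arrays between 13.3% and 22.6% of the spots had a Cy5 signal no higher than their local background. The number of arrays limits the precision. Log2 ratios within a group correlated across probes at r from 0.54 to 0.86, where probes are not independent replicates. The median SE of a log2 difference was 0.28 for both concentrations at 4 h and 0.26 for both at 8 h.

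The comparison of 1 mg/ml coal tar with DMSO at 4 h asked which genes respond soon after a lower exposure. Cyp1a1, the AhR-driven enzyme that oxidises polycyclic hydrocarbons, rose at least 14.6-fold (probe A_51_P279693, n = 4 and 4, adjusted p 1.5e-06, higher on 3 of 3 shared days). Only a bound is given because its signal exceeded background on 0 of 4 DMSO arrays. Tiparp, an ADP-ribosyltransferase that is induced by AhR and restrains it, rose 6.98-fold (log2 2.80 ± 0.34, n = 4 and 4, adjusted p 2.8e-05, 3 of 3 days). Cpox, which makes a haem precursor, rose 3.41-fold (log2 1.77 ± 0.33, adjusted p 0.0183, 3 of 3 days). Bmp4, a growth factor of lung development, fell by 1.21 log2 (SE 0.25, n = 4 and 4, adjusted p 0.0389, lower on 3 of 3 days).

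In this comparison 20 probes passed, 17 higher and 3 lower, and 1458 of 14419 (10.1%) had an unadjusted p under 0.05. Other rises were those of the mitochondrial creatine kinase Ckmt1 (3.90-fold, adjusted p 0.0162), the sugar transporter Slc2a6 (3.61-fold, adjusted p 0.0013) and the NAD-synthesising Nmnat2 (3.26-fold, adjusted p 0.0318), each higher on 3 of 3 days. Nqo1, a quinone reductase shared by AhR and Nrf2, rose 2.70-fold (adjusted p 0.0271, 3 of 3 days). Gpc1, a heparan sulphate proteoglycan, rose 2.82-fold (n = 3 and 3, adjusted p 0.0389, 1 of 1 shared day). The interferon regulator Irf1 rose 2.30-fold (adjusted p 0.0024, 3 of 3 days). The water channel Aqp5 was also higher (adjusted p 0.0259, 3 of 3 days), but exceeded background on 0 of 4 DMSO arrays, and no fold is given because its bound lay above the fitted fold. Nmnat2 exceeded background on 1 of 4 DMSO arrays. Among the falls were Id1, an inhibitor of differentiation factors downstream of BMP (log2 -2.05 ± 0.40, n = 3 and 3, adjusted p 0.0389, 1 of 1 shared day) and saturated on 2 of 4 DMSO arrays, and the adhesion protein Pcdh7 (log2 -1.35 ± 0.24, adjusted p 0.0132, 3 of 3 days). Cyp1b1 did not pass (log2 1.59 ± 0.40, adjusted p 0.181, higher on 2 of 2 days).

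Cyp1a1, Tiparp, Slc2a6 and Irf1 passed without each of the 8 arrays in turn. The other 9 named genes that passed at 1 mg/ml and 4 h each lost the call without some array, from 3 arrays for Ckmt1 to all 8 for Id1 and Gpc1 (adjusted p 0.0511 to 0.246). The count of 20 became 8, 11, 6 and 6 without DMSO replicates 1, 2, 3 and 5, and 7 and 5 without coal tar replicates 1 and 3. With the quantification session as a block 9 of the 13 named genes lost the call, Irf1 and Nqo1 among them (adjusted p 0.0763 to 0.239), and with the day as a block Gpc1 did (adjusted p 0.062). Under at least 1 alternative 11 of the 13 lost it, with adjusted p up to 0.715, including Slc2a6 with Cy5 alone (0.309). Within session 1, which holds 1 coal tar and 2 DMSO arrays, Cyp1a1 was higher, Tiparp by 1.88 and Cpox by 0.83 log2, while Bmp4 differed by -1.33. Median centring moved the median of all genes by 0.109 log2 in this comparison and gave 18 rises and 0 falls (limma), and the Cy5 channel alone gave 13 and 0.

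Among the lists at 1 mg/ml and 4 h, the AhR battery (11 genes) rose by a mean of 1.09 log2 and a median of 0.73 (adjusted p 4.4e-08, 4 of 4 arrays). Of its members 3 passed over all probes and 5 when adjusted over the list alone. The 23 cholesterol synthesis genes fell by 0.49 on average (median -0.41, adjusted p 2.8e-07, 4 of 4 arrays between -0.74 and -0.31), with 0 passing over all probes in limma and 5 adjusted over the list alone. Ribosomal protein genes fell by 0.31 (22 genes, median -0.36, adjusted p 0.00032, 4 of 4 arrays), with 0 passing in limma either way. Without day 2, 4 or 5 the ribosomal list lost the call (adjusted p 0.144, 0.181 and 0.209), with means of -0.17, -0.14 and -0.18. With an estimated correlation the adjusted p of the AhR, cholesterol and ribosomal lists were 0.0039, 0.0485 and 0.0205. Heat shock genes fell by 0.16 (21 genes, median -0.22, adjusted p 0.0472, lower in 3 of 4 arrays), and lost the call with an estimated correlation (adjusted p 0.332). Heat shock also lost it without day 2, 3 or 5 (adjusted p 0.0988, 0.291 and 0.357) and without coal tar replicate 3 (adjusted p 0.0752), within a range of 0.00636 to 0.357 over its alternatives. Its mean ran from -0.33 with the session as a block to -0.059 without day 5, and was -0.26, -0.10 and -0.25 without days 1, 3 and 4 and -0.10 with median centring. Within session 1 the means were 0.82 for the AhR battery, -0.40 for cholesterol synthesis, -0.25 for ribosomal proteins and -0.44 for heat shock.

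The comparison of 4 mg/ml coal tar with DMSO at 4 h asked the same of the higher exposure. Cyp1a1 rose at least 7.66-fold (n = 4 and 4, adjusted p 3.1e-05, 3 of 3 days) and Tiparp 6.91-fold (log2 2.79 ± 0.34, adjusted p 3.1e-05, 3 of 3 days). Insig1, which holds the sterol regulator SREBP in the endoplasmic reticulum and is itself a target of it, fell by 2.00 log2 (SE 0.33, n = 4 and 3, adjusted p 0.0097, lower on 2 of 2 days). The monocyte attractant Ccl7 fell by 1.55 log2 (SE 0.27, n = 4 and 4, adjusted p 0.0162) and the macrophage growth factor Csf1 by 1.40 log2 (SE 0.26, adjusted p 0.0162), both on 3 of 3 days. Cpox (3.82-fold, adjusted p 0.0097, 3 of 3 days), Gpc1 (3.01-fold, adjusted p 0.0162, 2 of 2 days) and the neurotrophin receptor Ntrk2 (2.78-fold, adjusted p 0.0162, 3 of 3 days) also rose. Ntrk2 exceeded background on 3 of 4 coal tar and 1 of 4 DMSO arrays.

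These 8 probes, 5 higher and 3 lower, were all that passed with 4 mg/ml at 4 h. An unadjusted p under 0.05 was reached by 516 (3.58%), fewer than the share of 0.05 expected with no change. Cyp1a1 and Tiparp passed without each of the 8 arrays, while the other 6 genes each lost the call without 3 to 6 of them (adjusted p 0.0559 to 0.163). The count became 2 and 4 without DMSO replicates 1 and 5, and 3, 2 and 3 without coal tar replicates 2, 3 and 5. With the session as a block Cpox (adjusted p 0.085) and Csf1 (adjusted p 0.119) lost the call, and with the day as a block Ccl7 did (adjusted p 0.0534). Over all alternatives the adjusted p of these 6 genes reached 0.767, for Ntrk2 with Cy5 alone, which gave a log2 value of 0.92. Within sessions 1 and 6 Cyp1a1 was higher, and within session 1 Insig1 differed by -1.53, Ccl7 by -1.56 and Csf1 by -1.36. The split of 5 rises and 3 falls became 4 and 1 with median centring and 3 and 1 with Cy5 alone.

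Cholesterol synthesis had the smallest camera p of the lists with 4 mg/ml at 4 h and fell by 0.73 on average (median -0.78, adjusted p 6.8e-22, 0.00043 with an estimated correlation, 4 of 4 arrays between -1.12 and -0.22). Of its genes 1 passed over all probes, Insig1, and 12 adjusted over the list alone. The AhR battery rose by 0.94 (median 0.45, adjusted p 1.3e-10, 0.0011 with an estimated correlation, 4 of 4 arrays), with 2 members passing over all probes and 5 adjusted over the list alone. Unfolded protein response and ATF4 genes rose by 0.20 (39 genes, median 0.15, adjusted p 0.0013, 0.0039 with an estimated correlation, 4 of 4 arrays), with 0 passing over all probes in limma and 2 adjusted over the list alone. Mitosis genes rose by 0.17 (39 genes, median 0.24, adjusted p 0.0083, 3 of 4 arrays), which was lost with an estimated correlation (adjusted p 0.418) and without day 1 or 4 (adjusted p 0.156 and 0.106, means 0.11 and 0.11), while without day 2 the mean was 0.26. Fatty acid genes fell by 0.14 (25 genes, median -0.14, adjusted p 0.039, 4 of 4 arrays), with an adjusted p of 0.0906 by the estimated correlation and 0.0738 with the session as a block. Without days 1, 2, 3 and 4 it was 0.0766, 0.0874, 0.12 and 0.0889. Within sessions 1 and 6 the means were -0.75 and -0.86 for cholesterol synthesis, 1.04 and 0.89 for the AhR battery, and 0.33 and 0.11 for the unfolded protein response. They were 0.090 and 0.20 for mitosis, and -0.12 in both sessions for fatty acids.

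**Figure D1:**
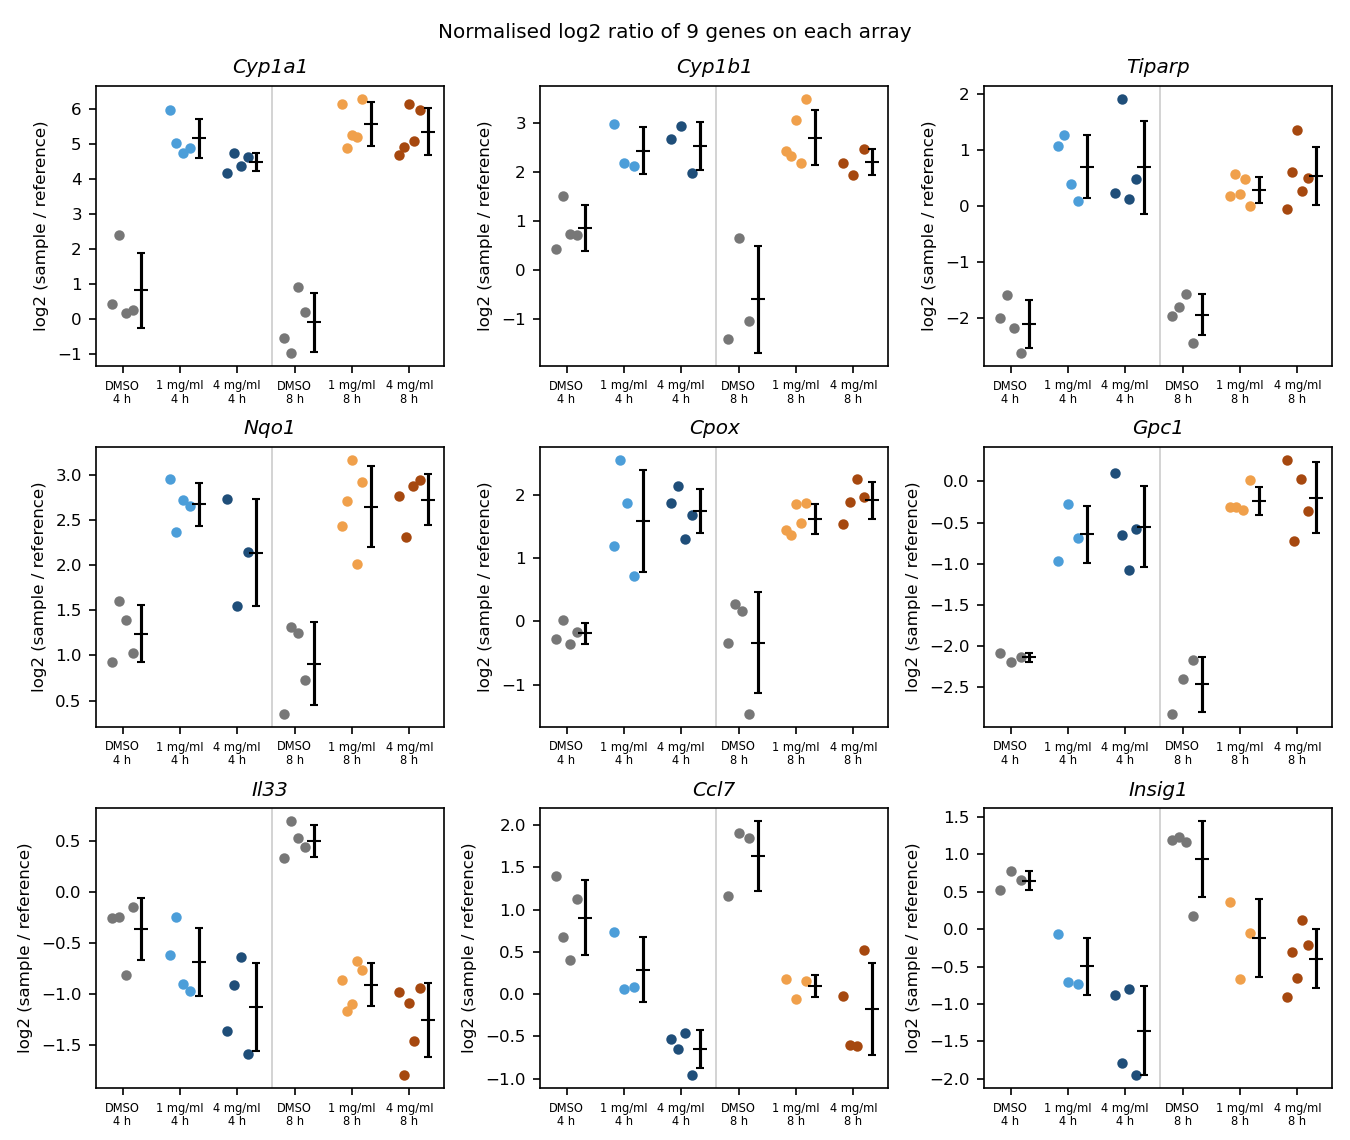
Log2 ratio of sample over reference (vertical axis) of 9 genes on each of the 26 arrays in the 6 groups (horizontal axis), with the mean and SD of each group. Cyp1a1, not above background on the DMSO arrays, rises at least 14.6- and 7.66-fold at 4 h and at least 40.5- and 25.5-fold at 8 h with 1 and 4 mg/ml. In the same order Il33 falls at 8 h by 1.41 and 1.75 log2 (2.66- and 3.37-fold). The Cyp1a1 bounds are set by the background limit and are given without a sampling error.

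The comparison of 1 mg/ml with DMSO at 8 h asked what the lower exposure had changed after a longer incubation. Cyp1a1 rose at least 40.5-fold (n = 5 and 4, adjusted p 8.2e-10, 4 of 4 days, with 0 of 4 DMSO arrays above background). Cyp1b1, a second AhR-driven oxidase that activates hydrocarbons, rose 9.81-fold (log2 3.29 ± 0.39, n = 5 and 3, adjusted p 8.0e-05, 3 of 3 days). The epithelial alarm cytokine Il33 fell by 1.41 log2 (SE 0.22, n = 5 and 4, adjusted p 0.0011, lower on 4 of 4 days), and Ccl7 by 1.54 log2 (SE 0.31, n = 3 and 3, adjusted p 0.0257, 2 of 2 days). Nqo1 rose 3.33-fold (log2 1.74 ± 0.26, n = 5 and 4, adjusted p 0.00087, 4 of 4 days), with 2 of 5 coal tar arrays saturated.

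In this comparison 44 probes passed, 37 higher and 7 lower. An unadjusted p under 0.05 was reached by 755 (5.24%), close to the share of 0.05 expected with no change. Tiparp and Gpc1 each rose 4.69-fold (adjusted p 0.0003 on 4 of 4 days and 0.00014 on 2 of 2), Tbc1d16, which switches off Rab proteins, 4.58-fold (adjusted p 0.0238, 4 of 4 days) and Cpox 3.88-fold (adjusted p 0.0014, 4 of 4 days). Ckmt1 (3.52-fold, adjusted p 0.0082), Nmnat2 (2.81-fold, adjusted p 0.0296), Aqp5 (2.43-fold, adjusted p 0.002) and Irf1 (1.83-fold, adjusted p 0.0233) were higher on 4 of 4 days. Among the falls, each on 4 of 4 days, were the hyaluronan-degrading Cemip (log2 -1.20, adjusted p 0.0406), the collagen hydroxylase Plod2 (-1.03, adjusted p 0.0201), the integrin adaptor Bcar3 (-1.11, adjusted p 0.0406) and the membrane-skeleton protein Add3 (-1.26, adjusted p 0.0327). The other probe for Cemip gave -0.026 (adjusted p 0.999). Signal exceeded background on 3 of 4 DMSO arrays for Ckmt1, 2 of 4 for Nmnat2 and Cyp1b1 and 1 of 4 for Aqp5, and on 4 of 5 coal tar arrays for Add3, while Gpc1 was saturated on 1 of 5 coal tar arrays.

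Of 17 named genes that passed with 1 mg/ml at 8 h, 8 passed without each of the 9 arrays, namely Cyp1a1, Cyp1b1, Tiparp, Gpc1, Cpox, Nqo1, Il33 and Aqp5. The other 9 each lost the call without some array, from 1 for Ckmt1 (DMSO replicate 2, adjusted p 0.0729) to all 9 for Cemip, with adjusted p from 0.0503 to 0.226 over these genes. The count of 44 became 26, 21 and 29 without DMSO replicates 1, 2 and 3, and 24 and 26 without coal tar replicates 4 and 5. With the session as a block 7 of the 17 lost the call (adjusted p 0.071 to 0.444), and with the day as a block Bcar3 did (adjusted p 0.0584). Under at least 1 alternative 11 of the 17 lost it, with adjusted p up to 1.00, including Il33 with Cy5 alone (0.2) and Aqp5 under 4 of 31 (up to 0.0843). Within sessions 1 and 6 Cyp1a1 was higher in both.

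The AhR battery rose by a mean of 1.54 log2 with 1 mg/ml at 8 h (median 1.37, adjusted p 2.6e-22, 3.2e-05 with an estimated correlation, 5 of 5 arrays), with 5 of 11 members passing over all probes and 6 adjusted over the list alone. Nrf2 antioxidant genes rose by 0.22 (28 genes, median 0.22, adjusted p 0.0027, 0.0485 with an estimated correlation, 5 of 5 arrays), with Nqo1 as the 1 member that passed by either adjustment. That list's adjusted p was 0.055 with the session as a block and 0.072 without day 3. Interferon response genes rose by 0.28 (34 genes, median 0.28, adjusted p 0.0001, 0.339 with an estimated correlation, 5 of 5 arrays), with 1 member, Irf1, passing over all probes and 1 adjusted over the list alone. With the session as a block the interferon mean was 0.49. G1/S genes fell by 0.26 (40 genes, median -0.24, adjusted p 3.3e-05, 4 of 5 arrays), mitosis genes by 0.20 (39 genes, median -0.21, adjusted p 0.0036, 4 of 5 arrays) and cholesterol genes by 0.30 (23 genes, median -0.24, adjusted p 0.0014, 5 of 5 arrays). With an estimated correlation these 3 lists, like interferon, lost the call (adjusted p 0.125 for G1/S, 0.396 for mitosis and 0.242 for cholesterol). The mitosis mean was -0.51 without the weak arrays, -0.31 without day 4 and -0.091 with median centring, and the Nrf2 mean was 0.34 without the weak arrays. Mitosis also lost the call without day 1 or 5 (adjusted p 0.144 and 0.0602), and cholesterol without day 5 (0.138). Over all probes 0 members of the last 3 passed in limma, and adjusted over the list alone 0, 1 and 2 did. Within sessions 1 and 6 the means were 2.05 and 1.72 for AhR, 0.16 and 0.13 for Nrf2, 0.50 and 0.38 for interferon, -0.26 and -0.15 for G1/S, -0.53 and -0.029 for mitosis, and -0.36 and -0.48 for cholesterol.

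The comparison of 4 mg/ml with DMSO at 8 h asked the same of the higher exposure. Sterol genes stood out among the falls: the isopentenyl isomerase Idi1 fell by 1.99 log2 (SE 0.32, n = 5 and 4, adjusted p 0.0014), the squalene epoxidase Sqle by 1.45 log2 (SE 0.22, adjusted p 0.00082) and the sterol reductase Hsd17b7 by 2.27 log2 (SE 0.40, adjusted p 0.0037), each on 4 of 4 days. Elovl6, which lengthens fatty acids, fell by 1.71 log2 (SE 0.27, adjusted p 0.00098, 4 of 4 days). Il33 fell by 1.75 log2 (SE 0.22, adjusted p 7.3e-05, 4 of 4 days) and Ccl7 by 1.81 log2 (SE 0.29, n = 4 and 3, adjusted p 0.0024, 3 of 3 days). Cyp1a1 rose at least 25.5-fold (n = 5 and 4, adjusted p 2.0e-09, 4 of 4 days) and Cyp1b1 6.96-fold (n = 3 and 3, adjusted p 0.0014, 1 of 1 shared day).

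A total of 54 probes for 53 genes passed with 4 mg/ml at 8 h, 23 higher and 31 lower, and 971 (6.73%) had an unadjusted p under 0.05. With the exposure day as a block 107 passed, including all 54. Tiparp (5.58-fold, adjusted p 7.3e-05, 4 of 4 days), Gpc1 (4.83-fold, adjusted p 7.3e-05, 3 of 3), Cpox (4.76-fold, adjusted p 0.00043, 3 of 3), Nqo1 (3.51-fold, adjusted p 0.00082, 3 of 3) and Aqp5 (2.84-fold, adjusted p 0.00025, 4 of 4) were higher. Falls outside sterol synthesis included Phldb2, which anchors microtubules at the cell edge (log2 -2.12 ± 0.37, adjusted p 0.0029, 4 of 4 days), Pcdh7 (-1.43, adjusted p 0.0024, 3 of 3) and Bcar3 (-1.43, adjusted p 0.003, 4 of 4). The gap junction protein Gja1 exceeded background on 0 of 5 coal tar arrays and was at least 1.98-fold lower (adjusted p 0.0038, 4 of 4 days). Insig1 was lower by 2.52-fold (log2 -1.33 ± 0.29, adjusted p 0.0349, 4 of 4 days), Pmvk at -1.08 (adjusted p 0.0203) and Add3 at -1.22 (adjusted p 0.038), while Irf1 was 1.80-fold higher (adjusted p 0.024), each on 4 of 4 days. Cemip fell by 1.51 (adjusted p 0.0036, 4 of 4 days), though not on its other probe (-0.25), and was at -2.39 with Cy5 alone. Ebpl passed (adjusted p 0.038), but exceeded background on 0 of 5 coal tar and 1 of 4 DMSO arrays, and no fold is given because its bound was under 1. Bmp2k, a kinase, passed by 1 probe (-1.72, adjusted p 0.017, 4 of 4 days), although its groups overlapped, while its other probe gave -0.60 and did not pass. On the coal tar arrays signal exceeded background on 4 of 5 for Pcdh7, Insig1, Ccl7, Add3 and Elovl6, 3 of 5 for Bmp2k and 2 of 5 for Phldb2. On the DMSO arrays it did on 3 of 4 for Gja1, 2 of 4 for Cyp1b1 and 1 of 4 for Aqp5. Nqo1 was saturated on 1 of 5 coal tar arrays and Idi1 on 1 of 4 DMSO arrays.

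Of the 24 named genes that passed with 4 mg/ml at 8 h, 18 did so without each of the 9 arrays, including Idi1, Sqle, Hsd17b7, Elovl6, Il33 and Ccl7. Insig1, Add3, Irf1, Pmvk, Bmp2k and Ebpl each lost the call without 3 to 7 arrays (adjusted p 0.0542 to 0.196). With the session as a block only Irf1 of the 24 lost it (adjusted p 0.058, within 0.00897 to 0.318 over its alternatives). Under at least 1 alternative 16 of the 24 lost the call, with adjusted p up to 0.999. They included Hsd17b7 under 4 of 32 (up to 0.172), Ccl7 under 2 of 31 (up to 0.118) and Sqle under 1 of 32 (0.0736). Within sessions 1, 5 and 6 Cyp1a1 was higher in each. Il33 differed by -1.90, -1.61 and -1.90, and Hsd17b7 by -1.59, -2.32 and -3.84.

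The cholesterol synthesis list fell by 0.93 on average with 4 mg/ml at 8 h (median -1.03, adjusted p 8.1e-23, 0.00041 with an estimated correlation), with 5 of 5 coal tar arrays between -1.20 and -0.79 and the DMSO arrays between -0.13 and 0.092. Of its 23 genes 7 passed over all probes and 15 adjusted over the list alone. The AhR battery rose by 1.43 (median 1.11, adjusted p 1.1e-17, 5.2e-05 with an estimated correlation, 5 of 5 arrays), with 5 passing over all probes and 6 adjusted over the list alone. Inflammatory cytokines fell by 0.31 (25 genes, median -0.092, adjusted p 0.0067, 0.234 with an estimated correlation, 5 of 5 arrays), a mean carried by few genes, with Il33 and Ccl7 the 2 passing over all probes and 5 adjusted over the list alone. G1/S genes fell by 0.21 (median -0.17, adjusted p 0.0025, 0.27 with an estimated correlation, 5 of 5 arrays) with 0 passing in limma either way. Extracellular matrix genes fell by 0.20 (35 genes, median -0.22, adjusted p 0.0198, 0.125 with an estimated correlation, 5 of 5 arrays) with 0 passing over all probes in limma and 1 adjusted over the list alone. These 3 lists thus lost the call with an estimated correlation. Without the weak arrays inflammatory genes (adjusted p 0.0515) and G1/S (0.256) lost it too, as did inflammatory genes without day 1 or 4 (0.0725 and 0.0529) and G1/S without day 3 (0.0995, mean -0.13). The matrix list also lost it without day 1, 2, 3 or 5 (adjusted p 0.0766, 0.111, 0.0813 and 0.0602), with the day as a block (adjusted p 0.11) and with the session as a block (0.0803), within 0.0119 to 0.125 over its alternatives. Within sessions 1, 5 and 6 the means were -0.91, -1.05 and -1.09 for cholesterol, 1.36, 1.39 and 1.68 for AhR and -0.27, -0.21 and -0.53 for inflammatory genes. They were -0.15, -0.45 and -0.19 for G1/S and -0.17, -0.19 and -0.14 for matrix.

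Targets of p53 and stress markers were followed because hydrocarbons in coal tar damage DNA once oxidised. The growth arrest gene Cdkn1a did not pass, at 0.75 ± 0.26 with 1 mg/ml at 8 h (n = 5 and 4, adjusted p 0.626, higher on 4 of 4 days) and 0.42 with 4 mg/ml at 8 h (adjusted p 0.874, 4 of 4 days). At 4 h it gave -0.30 and 0.22, the former turning to 0.082 with Cy5 alone. Mdm2, the p53 antagonist, stayed between -0.46 and 0.0019 in the 4 comparisons, with a change of sign by Cy5 alone for 4 mg/ml at 4 h (0.36) and 1 mg/ml at 8 h (-0.068), and the haem oxygenase Hmox1 between 0.13 and 0.84 (adjusted p 0.924 to 1.00). Mdm2 exceeded background on 3 of 4 arrays with 1 mg/ml at 4 h and 4 of 5 with 4 mg/ml at 8 h, and Hmox1 was saturated on 1 of 4 with 4 mg/ml at 4 h. The 28 p53 targets as a list had mean shifts of 0.060, 0.13, 0.024 and 0.10 and did not pass by camera (adjusted p 0.926, 0.156, 0.478 and 0.175, in the order 1 and 4 mg/ml at 4 h, then 8 h).

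Of 100 list tests 20 passed, 8 higher and 12 lower, and 10 held with an estimated correlation. The means of the AhR battery include the fitted value of Cyp1a1, which was not above background in DMSO. Without the filter on dim probes the mean of the AhR battery was 0.65 and 0.54 for 1 and 4 mg/ml at 4 h and 1.01 for 1 mg/ml at 8 h. With median centring the ribosomal mean at 1 mg/ml and 4 h was -0.17, and at 1 mg/ml and 8 h the means were -0.16 for G1/S and 0.35 for Nrf2. Besides the p53 list, 12 lists passed by camera in no comparison, with mean shifts between -0.19 and 0.25. Their adjusted p ran from 0.185 to 0.926 for DNA repair, 0.096 to 0.919 for histones, 0.0613 to 0.241 for other secreted factors and 0.175 to 0.805 for hypoxia and glycolysis. They ran from 0.065 to 0.733 for immediate early genes, 0.154 to 0.482 for metallothioneins and phase II transferases, and 0.185 to 0.876 for circadian genes. For cell type markers they ran from 0.0872 to 0.381 for lung epithelium, 0.426 to 0.636 for general epithelium, 0.167 to 0.956 for mesenchyme, 0.241 to 0.926 for leukocytes and 0.65 to 0.896 for endothelium. None of the lists with a sign that differed between median, mean and test passed. For 1 mg/ml at 4 h these were G1/S (mean -0.034, median 0.00045), inflammatory (-0.034 and 0.037), immediate early (0.027 and -0.097) and endothelial genes (0.025 and -0.0018), and the test pointed down for Nrf2 (mean 0.023, median 0.030) and fatty acids (0.021 and 0.077). At 4 mg/ml and 4 h they were inflammatory (-0.076 and 0.051) and endothelial genes (0.0002 and -0.0052). At 1 mg/ml and 8 h they were p53 targets (0.024 and -0.020), histones (-0.019 and 0.0034) and endothelial genes (0.022 and -0.046). At 4 mg/ml and 8 h they were DNA repair (-0.0061 and 0.011), fatty acid (-0.13 and 0.026), immediate early (0.057 and -0.0037) and mesenchymal genes (-0.0098 and 0.046).

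**Figure D2:**
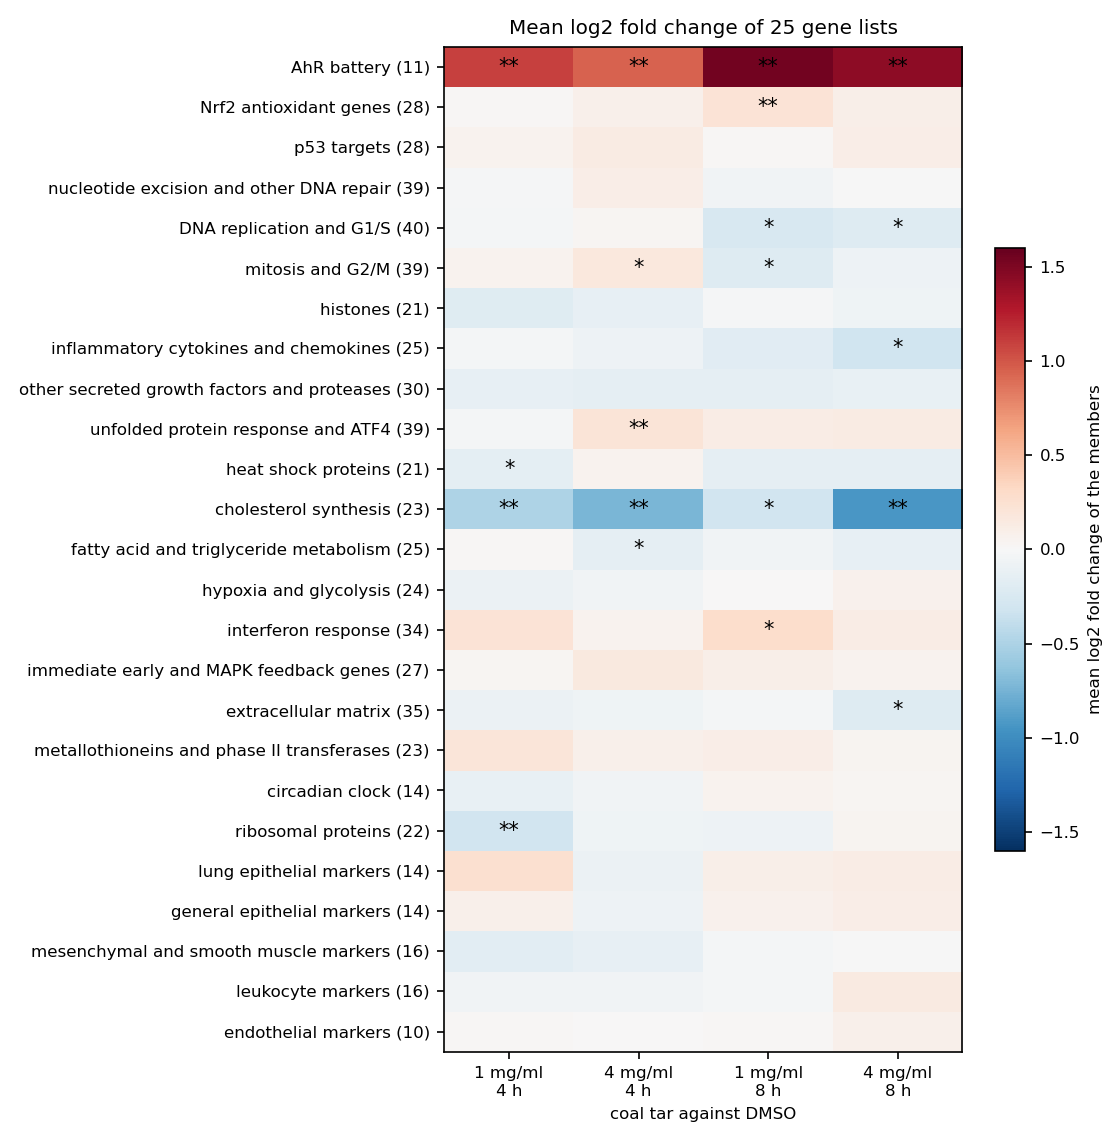
Mean log2 fold change (colour) of the 25 gene lists (vertical axis) in the 4 coal tar comparisons (horizontal axis), with 1 star where the adjusted p is under 0.05 and 2 stars where an estimated correlation gives the same call. The AhR battery is higher in all 4 (0.94 to 1.54) and cholesterol synthesis lower in all 4 (-0.93 to -0.30).

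Cyp1a1, Tiparp, Cpox and Gpc1 passed in all 4 coal tar comparisons, and 79 probes passed in at least 1. At 4 h the concentrations shared 4 probes, all higher, where independent lists would share 0.0059. The fold changes correlated across probes at r = 0.34, below the 0.50 that simulations gave from the shared DMSO arrays alone (covariance 0.036 against 0.042). With the DMSO arrays split so that each concentration had its own, they shared 2 in each of 6 splits. At 8 h the concentrations shared 26 probes, 20 higher and 6 lower, where independent lists would share 0.059 and 0.015, and 47 with the day as a block. There r was 0.71 against 0.56 in simulations (covariance 0.071 against 0.042), and split DMSO arrays gave 4 to 9 shared probes and a mean r of 0.050. At both times the simulated values took no account of the exposure days that the concentrations share, within which residuals were correlated. Between times 14 probes were shared at 1 mg/ml, all higher, and 6 at 4 mg/ml, 4 higher and 2 lower.

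The comparison of 4 with 1 mg/ml asked which genes depend on concentration. Among the genes with the smallest p at 8 h were Sqle (-0.90 ± 0.21), Elovl6 (-1.06 ± 0.25), Pmvk (-0.89 ± 0.21) and Idi1 (-1.25 ± 0.30), each lower at 4 mg/ml on 5 of 5 days. None passed, with adjusted p of 1.00 each and unadjusted p from 0.00019 to 0.00028. By limma 0 probes passed at 8 h, with 421 (2.92%) at an unadjusted p under 0.05, fewer than expected with no change. At 4 h 0 passed and 1640 (11.4%) had an unadjusted p under 0.05. The smallest p at 4 h belonged to the carboxylase Ggcx (-1.15 ± 0.23), the sphingomyelin synthase Sgms2 (at least 1.35-fold higher), the tRNA synthetase Eprs (1.30 ± 0.29), the glycosyltransferase Mgat3 (-1.22 ± 0.27) and the death-signalling kinase Ripk1 (1.56 ± 0.35), each in its direction on 3 of 3 days with adjusted p 0.242. The other probes gave -0.093 for Mgat3 and 0.53 for Eprs. On the 1 mg/ml arrays Sgms2 exceeded background on 0 of 4 and Ripk1 on 3 of 4, and on the 4 mg/ml arrays Sgms2 did on 2 of 4. Without 1 mg/ml replicate 5 the count at 4 h was 3, with Ggcx and Ripk1 at an adjusted p of 0.0356, and without 4 mg/ml replicate 4 it was 1 (adjusted p of these genes up to 1.00 over the alternatives). Cyp1a1 did not differ detectably between concentrations, at -0.68 ± 0.44 at 4 h (adjusted p 0.565, 3 of 3 days) and -0.21 ± 0.39 at 8 h (adjusted p 1.00, 3 of 5 days).

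Whether effects changed between 4 h and 8 h was tested as an interaction, and 0 probes passed by limma for either concentration. At an unadjusted p under 0.05 were 536 (3.72%) for 1 mg/ml and 513 (3.56%) for 4 mg/ml, fewer than expected with no change. For Cyp1a1 no value of this change is given, since 0 of 4 DMSO arrays exceeded background at either time, and it did not pass (adjusted p 0.997 and 1.00). Cyp1b1, which passed at 8 h and not at 4 h, changed by 1.71 ± 0.56 (p 0.0055, adjusted p 0.997) and 1.11 ± 0.59 (p 0.0715, adjusted p 1.00), and Il33 by -1.09 ± 0.32 (p 0.0022, adjusted p 0.997) and -0.99 ± 0.32 (p 0.0047, adjusted p 1.00). The mean log2 ratio of Cyp1b1 at 4 h and 8 h was 0.85 and -0.59 in DMSO. With coal tar it was 2.44 and 2.70 at 1 mg/ml and 2.54 and 2.20 at 4 mg/ml. For Il33 the means were -0.37 and 0.50 in DMSO, -0.69 and -0.91 at 1 mg/ml, and -1.13 and -1.26 at 4 mg/ml. In these means the larger part of the changes lay in the DMSO arrays. For Cyp1b1 the DMSO mean at 8 h rests on 3 values (SD 1.10), and its signal exceeded background on 2 of 4 arrays. DMSO 8 h replicates 3 and 5 were also weak arrays, with 19.6% and 13.3% of spots not above local background. The other genes with the smallest p at 1 mg/ml were Spg11, Lhfpl2, Sgms2 and Psg19, none of which passed. At 4 mg/ml they were Bmp2k (-1.97), Gja1, Aif1l (1.10), Amotl1 (-1.35) and Spg11, and none passed. The probes given without a value had a group in which 0 arrays exceeded background. Other probes gave -0.20 for Bmp2k and -0.77 for Amotl1 at 4 mg/ml, and -0.19 and -0.29 for Spg11 at 1 and 4 mg/ml.

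The DMSO arrays at 8 h and 4 h were compared to see how the cells change without coal tar. By limma 0 probes passed and 371 (2.57%) had an unadjusted p under 0.05, fewer than expected with no change. The cold-induced RNA-binding gene Cirbp had the smallest p (-1.10 ± 0.23, adjusted p 0.666, lower on 4 of 4 days), saturated on 1 of 4 arrays at 4 h. Next were the receptor subunit Gabra4 (at least 1.36-fold higher, 3 of 4 days), Il33 (0.86), the kinase Ulk4 (0.84) and the sterol isomerase relative Ebpl (0.87), the last 3 higher on 4 of 4 days and with adjusted p of 1.00 each. At 4 h and 8 h Gabra4 exceeded background on 0 and 2 of 4 arrays, Ulk4 on 1 and 3 and Ebpl on 1 and 1. With Cy5 alone Ulk4 (-0.036) and Ebpl (-0.026) changed sign. Without the DMSO 8 h replicate 1 array 1 probe passed.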

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

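Chosen only after the result was seen were the tests of coal tar RNA mixed into a control and of exchanged image files, while the other tests of this part were planned.

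Cyp1a1 on the DMSO 4 h replicate 2 array had a log2 ratio of 2.41, against 0.19 to 0.45 on the other 3 arrays of its group, with a Cy5 signal of 824.5 over a background of 329 and no array of the 4 above the background limit. With background correction left out, the gap to the others was 0.488 of the group's range, against 0.884 with it, which is consistent with a spot signal close to background. Coal tar RNA mixed into this sample could also raise the ratio. A share of 14.0%, which the ratio would need, predicts a median shift of 0.19 in 43 other probes raised by coal tar, and the shift was 0.056, beside -0.12 to 0.027 in the other arrays (SD 0.073), so a mixture and a noisy spot cannot be told apart. No biological explanation was tested, since the design gives none within a control group.

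Fewer probes had an unadjusted p under 0.05 with 4 mg/ml than with 1 mg/ml at 4 h, 516 against 1458. A single unusual 1 mg/ml array may contribute, but without replicate 3, whose loss lowers the count most, 879 remained against 551. With the quantification session as a block the counts were 1195 and 639. The 1 mg/ml count thus stayed the higher with either change. The array and the session were not removed together, and no spread was computed for the gap between the counts. Whether the array or the session accounts for the gap, alone or jointly, therefore cannot be told. The concentration itself stays open as a biological explanation. Of the 35 groupings of the 1 and 4 mg/ml arrays 2, the real one included, gave 1640 or more probes between them (highest other 1817), so chance was not excluded. The 8 that part as many days are too few for a share under 0.05 (highest other 1554).

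The file headers of 2 arrays carry image numbers that are each other's label numbers, 1 from a coal tar group and 1 from a DMSO group. Among 70 probes called without these arrays, 56 (80%, exact 95% interval 68.7 to 88.6) differed between them in the labelled direction, and Cyp1a1 read 4.63 on the coal tar array and 0.20, not above background, on the other. The interval takes the probes as independent, which probes on the same arrays are not, and the 2 arrays also differ in incubation time. The Cyp1a1 reading and the direction of most of these probes argue against files exchanged between the samples, and both arrays were kept as labelled.

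Regrouping the same arrays tested whether chance can be excluded. For 1 mg/ml at 4 h only the real grouping, 1 of 35, gave as many as 20 probes (highest other 1), and with 4 mg/ml at 4 h 1 of 35 gave as many as 8 (highest other 1). For 1 mg/ml at 8 h 1 of 100 drawn regroupings gave as many as 44 (highest other 12). For these 3 comparisons the share was under 0.05 among groupings that take no account of the shared days, with no adjustment over the 9 comparisons. Such groupings alone cannot exclude chance, since the real groups share days. The 8, 8 and 14 groupings that part as many days as the real one are too few for a share under 0.05, and their highest other count was 0. For 4 mg/ml at 8 h 5 of 100 gave as many as 54, so chance was not excluded by this count. The highest, 638, set the arrays of days 1 and 5 against those of days 2, 3 and 4, which points to a structure of the arrays by day. The 14 regroupings that part as many days as the real one are again too few (highest other 0), and the count with the day as a block was 107.

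Among the other comparisons the counts at an unadjusted p under 0.05 were matched often, and chance was excluded in none. For 4 against 1 mg/ml at 8 h 66 of 100 regroupings gave as many as 421 (highest other 1104), and the 16 that part as many days are too few for a share under 0.05 (highest other 913). For the change over time 67 of 100 gave as many as 536 at 1 mg/ml (highest other 2466) and 54 of 100 as many as 513 at 4 mg/ml (highest other 2624), and so did 34 and 31 of the 54 that part as many days. For DMSO at 8 h against 4 h 30 of 35 gave as many as 371, the highest, 2723, with days 1 and 5 against days 2 and 3, and the 8 that part as many days are too few for such a share (highest other 967).

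Single arrays far from the rest of their group were looked for among named genes, which marked 21 of 273 sets, where about 1 in 20 arises by chance. At 4 h Il33 was at -0.82 on DMSO replicate 3 (others -0.25 to -0.15), Irf1 at -0.88 on DMSO replicate 1 (-0.63 to -0.59), Nmnat2 at 2.37 on 1 mg/ml replicate 5 (2.95 to 3.06) and Hmox1 at 0.092 on 1 mg/ml replicate 1 (0.76 to 0.87). On the 4 mg/ml arrays at 4 h Tbc1d16 was at -0.78 on replicate 3 (1.24 to 1.52) and Hsd17b7 at 1.19 on replicate 4 (-0.46 to -0.24).

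In the DMSO 8 h group Insig1 was at 0.18 on replicate 5 (others 1.16 to 1.23), Ntrk2 at 0.40 and Mgat3 at -0.91 on replicate 3 (0.14 to 0.18 and -1.93 to -1.76), and Plod2 at 0.032 and Irf1 at -0.71 on replicate 2 (-0.55 to -0.46 and -0.37 to -0.32). On its replicate 1 Hsd17b7 was at 0.57 (1.97 to 2.24), Sgms2 at -0.75 (-0.10 to -0.0092) and Psg19 at 1.06 (0.30 to 0.41). On the 1 mg/ml arrays at 8 h Gpc1 was at 0.022 on replicate 5 (-0.35 to -0.30), Plod2 at -1.88 on replicate 1 (-1.36 to -1.17), and Lhfpl2 at -0.50 and Aif1l at -1.72 on replicate 2 (-1.29 to -1.13 and -2.12 to -2.09). On the 4 mg/ml arrays at 8 h Csf1 was at 0.66 on replicate 1 (0.019 to 0.17) and Hsd17b7 at -1.79 on replicate 4 (-0.54 to -0.081).

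Array measures stood apart in 4 of 30 sets. The share of spots with Cy5 not above local background was 3.49% on DMSO 4 h replicate 5 (others 0.0516 to 0.272), 21.7% on 1 mg/ml 4 h replicate 3 (0.0047 to 2.93) and 22.6% on 4 mg/ml 8 h replicate 3 (0.0281 to 1.23). The share of spots marked as outliers was 1.76% on 4 mg/ml 8 h replicate 4 (3.17 to 3.72).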

How the results depend on the processing

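Chosen only after the data were seen were the fits with outlier-marked spots kept, without the 2 arrays with exchanged image numbers and without the 5 weak arrays, and for lists also the session block and the fit without 1 mg/ml 4 h replicate 3. Cyp1a1 and Tiparp passed in each coal tar comparison under all 30 to 32 alternatives, and the AhR battery under all 13 of the lists. Cholesterol synthesis passed under 13 of 13 in each comparison except 1 mg/ml at 8 h, where 11 did. The exposure day as a block changed no call of a named gene or list other than those given with the results. Signal over background limited Cyp1a1, Gja1, Sgms2 and Gabra4 to fold bounds, left Aqp5 at 4 h, Ebpl with 4 mg/ml at 8 h and several changes over time without a value, and left Ahrr untested.

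For 1 mg/ml at 4 h (20 probes) Cy5 alone gave 13, no dim filter 12, array weights 47, the session block 4, only the compared groups 5 and no weak arrays 8. For 4 mg/ml at 4 h (8) median centring gave 5, Cy5 alone 4, signal on all arrays 4, only the compared groups 5 and no exchanged arrays 4. For 1 mg/ml at 8 h (44) Cy5 alone gave 27, the session block 29, only the compared groups 13 and no weak arrays 14. For 4 mg/ml at 8 h (54) the fixed day block gave 107, array weights 31, only the compared groups 13 and no weak arrays 24. Leaving out arrays or days gave 3 to 22, 2 to 12, 16 to 51 and 23 to 52 in the same order, those moving the count by over 1.5 times being 3 to 11, 2 to 4, 16 to 29 and 23 to 35. For 4 against 1 mg/ml at 4 h (0) array weights gave 1 and leave-outs up to 3, from 1, and at 8 h keeping outlier-marked spots gave 1. For DMSO at 8 h against 4 h leave-outs gave 0 to 1. An estimated correlation left 10 of 20 list calls. With split DMSO arrays 2 probes were shared at 4 h, against 4, and a mean of 6.17 at 8 h, against 26, where the day block gave 47. Leaving out a day ended the list calls given with the results. Heat shock lost its call under 9 of 13 alternatives and fatty acids under 8. Fits with only the compared groups or without arrays have fewer arrays, and for the others the cause was not tested.

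Changes of sign arose for genes that did not pass, and the cause was not tested. For Mdm2, 4 mg/ml coal tar vs DMSO at 4 h (-0.028), no background correction gave 0.032, Cy5 alone 0.36, the authors' values 0.064, array weights 0.0029, no exchanged arrays 0.00040 and leave-outs -0.14 to 0.053, those reversed being 0.00040 to 0.053. For Mdm2, 1 mg/ml coal tar vs DMSO at 8 h (0.0019), Cy5 alone gave -0.068, the day block -0.10 fixed and -0.025 random, array weights -0.045, no exchanged arrays -0.034, no weak arrays -0.062 and leave-outs -0.15 to 0.15, those reversed being -0.15 to -0.0068. For Mdm2, 4 mg/ml coal tar vs DMSO at 8 h (-0.054), array weights gave 0.032, the session block 0.044 and leave-outs -0.26 to 0.085, those reversed being 0.0013 to 0.085. For Cdkn1a, 1 mg/ml coal tar vs DMSO at 4 h (-0.30), Cy5 alone gave 0.082 and the session block 0.029. For Cdkn1a, 4 mg/ml coal tar vs DMSO at 4 h (0.22), no exchanged arrays gave -0.0031, as did leaving out 4 mg/ml replicate 5, the lowest of the leave-outs (highest 0.32). For Hmox1, 1 mg/ml coal tar vs DMSO at 4 h (0.13), array weights gave -0.014 and leaving out DMSO replicate 1 -0.054, the lowest of the leave-outs (highest 0.37). For Ulk4, DMSO 8 h vs 4 h, Cy5 alone gave -0.036, and for Ebpl, DMSO 8 h vs 4 h, -0.026.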

Other observations

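Chosen only after the result was seen were the tests of exposure-day genes and of cholesterol synthesis against concentration.

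Some genes of secreted growth factors and proteases differed between exposure days. The smallest p for the day belonged to Rbbp5, which is not of this kind and spanned 1.78 log2 between days (limma adjusted p 0.00199). The collagenase Mmp13 spanned 1.98 log2 between days (limma adjusted p 0.0021) and the stromelysin Mmp3 1.68 (adjusted p 0.0028), both highest on day 2, at 1.15 and 1.13 above their group means. These genes were chosen after their values were seen. Of the 30 other secreted growth factors and proteases tested, 6 (20%) passed for the day, against 480 of 12565 other genes (3.82%, Fisher's exact p 0.00086, adjusted p 0.0216 over 25 lists). Fisher's test takes genes as independent, which genes that move together between days are not, so this p may be too small. Mmp13 and Mmp3, seen beforehand, also count among the 6. None of the other 24 lists passed, among them mesenchymal markers (3 of 16, 18.8%, adjusted p 0.275), extracellular matrix (1 of 35) and inflammatory cytokines (0 of 25). The others of the 6 were Angptl4 (1.08), Fgf7 (1.04), Tgfb2 (1.24) and Timp1 (0.95). In all 543 of 14417 probes passed for the day, and 3005 had an unadjusted p under 0.05. Of these 543, 2 also passed in a coal tar comparison. With the quantification session in the same model 0 probes passed for the day and 1 for the session by limma (adjusted p 0.16 for Mmp13 and Mmp3). Differences between days were thus not separated from those between sessions. Whether the loss of calls came from overlap of day and session or from the added terms was not tested.

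Cholesterol synthesis genes were among those with the smallest p between concentrations at 8 h. A fall that grows with concentration was tested as a hypothesis, on all 23 genes of the list. At 8 h the list was lower at 4 than at 1 mg/ml by a mean of -0.63 (median -0.59, camera p 2.7e-05 with an estimated correlation, adjusted p 0.00136 over 50 tests), with 0 genes passing over all probes in limma and 12 adjusted over the list alone. At 4 h the mean was -0.24 and the p 0.163. A dependence on concentration may thus hold at 8 h, in data that also raised the question.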
